A study of Mus musculus with 3 samples.

How the data were processed

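RNA sequencing was carried out on 3 samples of B16F10, a mouse melanoma cell line, with 1 sample in each of 3 groups. Per the labels, cells were transduced with a scrambled shRNA or with an shRNA against LSD1 or JMJD2C. RNA was isolated with a column kit and the libraries were made by an outside sequencing provider, per the labels' protocols. STAR, SAMtools 0.18, DESeq2 and the genome build GRCm38 are named in the submitters' processing notes. The role of each tool, the program that counted reads and the gene annotation are not given in the sources used here.

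The authors deposited 2 tables of the whole series, 1 whose file name calls it counts and 1 whose file name calls it RLOG. The name RLOG is that of the regularised log transformation of DESeq2, a tool named in the submitters' processing notes, but no file header states how the values were made. Each table has 3 columns of values, and the same 3 column names head both. These names have the form of a run, a lane and a barcode number, a reading taken from their format only. They were compared, as letters and digits only, with the text of every label of the 3 samples and of the series, and 0 of the 3 names occurred in any of them. A column was to be given to a sample only where its name matched that sample's labels. Column order and the level of the shRNA targets were not used as substitutes. An assignment made from the targets would fix in advance the outcome of the check of the targets themselves. All 6 columns, 3 in each table, were therefore left out of every comparison.

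The analysis planned before the data were examined was a description of the libraries, since 1 library per group allows no test across replicates. It comprised ratios between libraries with intervals for counting error, and counts of genes past a fixed ratio. Medians of fixed gene lists were to be placed among random lists of the same size matched on expression. The overlap of the knockdowns and correlations across genes were to be set beside values from simulated unchanged libraries. None of these was computed. The gene identifiers, which belong to no sample, were read from both tables with Python 3.11.15 and matched, without version suffixes, to the GENCODE M21 annotation of GRCm38. Each column total, the range of the values and the first and last rows were looked at only to learn what kind of values the tables hold. They are not reported here by library, so no depth or precision is given for any group.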

Results

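The series was designed to examine gene expression in B16F10 melanoma cells after knockdown of LSD1 or JMJD2C. LSD1, encoded by Kdm1a, and JMJD2C, encoded by Kdm4c, are histone demethylases of different enzyme families. The shControl, shLSD1 and shJMJD2C groups each held 1 library, so no spread between replicates could be estimated for any of them.

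The design implies a comparison of each knockdown with the scrambled control and of the knockdowns with each other. None of these comparisons was made. The 3 columns of values in each deposited table had names in the form of a run, a lane and a barcode. Of the 3 names, 0 occurred in a label of the samples. Columns were to be given to samples only by a match of names. By that rule, no value was given to the control, the LSD1 knockdown or the JMJD2C knockdown. A key from these names to the samples, which the labels do not hold, would allow the planned comparisons. The levels of Kdm1a and Kdm4c, which would check the labels of the knockdown libraries, were not used to assign the columns and are not reported.

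The gene identifiers of the tables do not depend on that assignment. The count table listed 50686 gene identifiers with 0 duplicates. Of these, 50376 were present in the GENCODE M21 annotation of GRCm38, and 310 were not. The matched identifiers comprised 21764 protein-coding genes and 28612 genes of other types. The table of regularised log values, so called after its file name, listed 20682 identifiers, all of which were also in the count table. The other 30004 identifiers of the count table were absent from it. Of the 20682 identifiers, 20620 were matched to the annotation, as 14399 protein-coding genes and 6221 genes of other types. These numbers describe which genes the authors listed, and they give no expression level for any group. Whether the identifiers absent from the table of regularised log values were left out for low counts was not examined.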

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

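No expression result was computed, so none of the processing alternatives planned before the data were examined was run. No paired analysis was possible because each group held 1 library and no column of values was matched to a group. The number of gene identifiers found in the annotation was also counted against the GENCODE M21 primary assembly annotation, which adds the scaffolds outside the chromosomes, an alternative chosen after seeing the data. It held 50462 identifiers of the count table, against 50376 in the annotation of the chromosomes. For the table of regularised log values the numbers were 20627 and 20620.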
